A study of Caenorhabditis elegans with 28 samples.

How the data were processed

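Chromatin immunoprecipitation sequencing was deposited for 28 samples of L4 whole animals, per the labels: 14 immunoprecipitates and their 14 input samples. The lists analysed here are those of the 14 immunoprecipitates, and the inputs enter only through the authors' peak calling. Per the labels' protocols, 4 mg/mL extract and 10 µg of Flag or Myc antibody were used for each sample. Groups and replicate letters came from the sample titles, and the series design text calls the replicates biological. The labels are at odds on the antibody: samples titled Myc carry a Flag antibody, and both LAG-1 and Notch samples carry a Myc antibody. Which control belongs to which target is therefore unclear, and all 6 controls were pooled in the main comparisons, with each control group alone as a further comparison.

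Per the submitters' processing notes, CASAVA 1.8, Bowtie and HOMER were used with genome build ce10. Versions of the last tools are not given in the sources used here. Per the file headers, HOMER called peaks in each library separately against its own input, requiring at least a 4-fold excess over input and over the surrounding 10 kb, and removed peaks whose tags fell on over 2 times fewer unique positions than the caller anticipated. Per the file headers, the false discovery rate was 0.01 for LAG-1 and Notch lists and 0.001 for control lists, so that the lists of targets and controls were not called alike. Per the file headers, the authors scaled the immunoprecipitate to the input in 2 libraries (LAG-1 a and b) and the input to the immunoprecipitate in the other 12, so fold values describe peaks within a list.

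The normalized tag count of a peak is a signal per 10 M tags, per the file headers. The total tags of a peak are tag counts in the deposited lists, or a scaled signal in LAG-1 a and b, and the input tags are a scaled signal in the deposited lists. The deposited fold over input, fold over the local background and clonal fold are ratios computed by the authors' caller. The focus ratio, a fraction that is high where tags lie on the proper side of the peak centre for their strand, the peak score and the p-value of each peak also come from the authors' caller, per the file headers. The p-values of peaks were not used here. Every list held as many peaks as its header states.

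Peaks on the ce10 chromosomes were merged into regions where they overlapped by at least 1 bp, over the libraries of each comparison, and over all 14 for shared regions, so a region's ends and counts can differ slightly between comparisons. Overlap of 2 lists was the percent of merged regions of the smaller list also held by the other. The design had named the percent of its peaks, which differs little: 31.9% of peaks against 32.4% of regions for LAG-1 b and c. Chance overlap came from 1000 circular shifts of one list along each chromosome, whose length was taken as the highest peak end in any list. Mean log10 peak numbers, X chromosome shares and overlap within minus between groups were compared by exact two-sided permutation of the library labels, adjusted over 8 comparisons by the Benjamini-Hochberg method. Presence of each region was tested by Fisher's exact test with the same adjustment over all merged regions. Splits of 4 libraries against 6 allow no permutation p below 0.00952, and 4 against 3 none below 0.0571.

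Named regions followed a rule written before the data were examined, as were the tests and the alternatives not stated otherwise. For each target, the regions with a peak in at least 3 of 4 libraries and in no control were ordered by number of libraries and then by mean rank of the authors' fold within each library, and the first 20 were taken. Where fewer than 10 met this, regions in 2 libraries followed in the same order up to 20. The 5 regions with peaks in most of the 14 libraries were added. Parts of the rule that take genes were not run. The text gives the leading regions and summarises the others. The regions V from 11770127 and IV from 16656221 fall under the rule. The peaks beside the region at I from 10588173 were singled out after their values were seen.

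The replicate letters were not taken as pairs. Alternatives were a stricter fold, leaving out each library in turn, a replicate block, the same number of top peaks from every list, other overlap rules, a Jaccard index, other numbers of libraries required, 1 control group alone and unlogged peak numbers. Chosen after seeing the data were a common Poisson threshold for all lists (1.40e-05, the strictest in any header), leaving out the 3 libraries with over 5000 peaks, and leaving out stretches of low-focus peaks. Distance to transcription start sites, the LAG-1 binding motif, gene lists and gene assignment were planned and not run, because they need a ce10 genome or annotation, which was not used here. The gene table at hand (WBcel235) was of another assembly. The positions of some Notch pathway and marker genes, lst-1 and sygl-1 among them, had been looked up in it before the text was written, and no result uses them.

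Depth sets how small an enrichment can be called, and it differed between libraries, so the absence of a peak was not read as absence of binding. Input depth was estimated here, from the steps of the scaled input tags in 12 libraries and from the scaling of the immunoprecipitate in LAG-1 a and b. The functions were tested on simulated lists of the real sizes with 200 planted LAG-1 regions: 185 (92.5%) were recovered as present in at least 3 libraries and no control, with 0 false regions. These rates describe the simulated lists only, and the rates in the real lists were not measured. In the same simulation Fisher's exact test gave 0 regions after adjustment over 17709 and 197 at an unadjusted p under 0.05. In 100 simulations without an effect the shift test, the overlap test and the test of means passed 0.05 in 3, 9 and 7. These simulations did not use lists of the real sizes. The shift test had random regions, the overlap test uniform random numbers and the test of means normal random numbers. They check the functions and give no error rate for the real lists. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.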

Results

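Chromatin immunoprecipitation followed by sequencing was used to map where the Notch pathway contacts DNA in Caenorhabditis elegans L4 larvae grown at 20 °C. GLP-1 is the Notch receptor that maintains germline stem cells, and its intracellular domain enters the nucleus and acts with LAG-1, the DNA-binding protein of the CSL family. Tagged Notch protein was precipitated in 4 libraries (a, b, c and d) and tagged LAG-1 in 4 libraries (a, b, c and e). Control worms carried Flag- and Myc-tagged GFP, which gave 3 libraries titled Flag (a, b and c) and 3 titled Myc (a, c and d). Chromatin came from whole animals. Genes such as lst-1 and sygl-1 are known targets of GLP-1 signalling in germline stem cells, but peaks were not assigned to genes here, because the gene table used was of another assembly, and regions are named by their ce10 coordinates.

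The 14 immunoprecipitation libraries held 3.13 to 19.8 M tags and 28805 peaks in all, each list called by the authors against its own input. LAG-1 libraries held 505, 1533, 1085 and 1965 peaks at 18.6, 19.8, 11.23 and 9.37 M tags. Notch libraries a to d held 826, 44, 8261 and 302 peaks at 9.06, 14.9, 4.58 and 8.11 M tags. The Flag control libraries a, b and c held 127, 45 and 83 peaks at 16.8, 12.8 and 11.5 M tags. Myc control libraries a, c and d held 8078, 5824 and 127 peaks at 11.02, 3.13 and 8.98 M tags. Merged over all 14 lists, the peaks formed 24961 regions, of which 22560 had a peak in only 1 library. Most of the single-library regions came from Myc control a, Myc control c and Notch c, in each of which at least 89.1% of regions appeared in no other list.

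**Figure D1:**
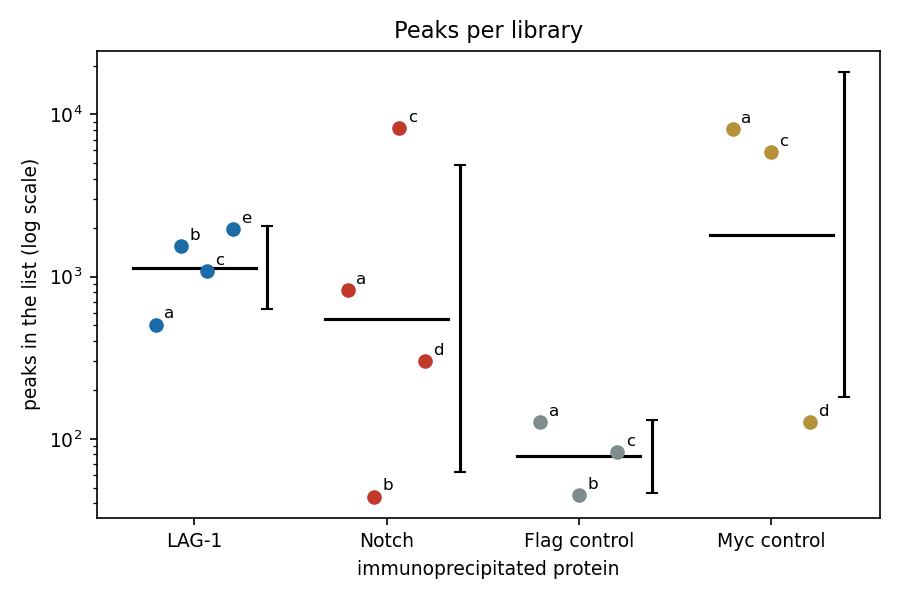
Number of peaks in each of the 14 lists on a log scale, by immunoprecipitated protein; letters mark replicates, horizontal lines the mean of the log10 numbers and bars 1 SD of the log10 numbers. The LAG-1 lists lie between 505 and 1965 peaks, while the Notch lists spread from 44 to 8261 and the Myc control lists from 127 to 8078.

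The first comparison asked which regions LAG-1 occupied beyond the tagged GFP controls. At 372 regions a peak was present in at least 3 of the 4 LAG-1 libraries and in none of the 6 controls, and 120 of these had a peak in all 4. The leading region, III from 9793659 to 9794000, had a fold over input of 47.6 ± 13.6 (SD, n = 4) and no Notch peak. Next came I from 10588173 to 10588504 at 51.4 ± 23.4 (SD, n = 4), which also carried a peak in 3 Notch libraries. The 4 LAG-1 lists shared 32.4% to 91.1% of the smaller list in each of the 6 pairs, against a mean of 1.10% after circular shifts of one list along the chromosomes.

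Further LAG-1 regions were III from 6344658 to 6345024 at a fold of 21.7 ± 8.77, I from 11977817 to 11978147 at 19.03 ± 8.82, IV from 17278352 to 17278756 at 18.2 ± 9.50 and IV from 16656221 to 16656619 at 17.1 ± 6.28 (SD, n = 4 each). On chromosome V, the regions from 15184084 to 15184421 and from 8413570 to 8413926 had folds of 16.05 ± 7.35 and 15.6 ± 7.10 (SD, n = 4). The first 20 regions in the ranking all had a peak in every LAG-1 library, with mean folds of 11.18 to 51.4 and lengths of 331 to 600 bp. Of these 20, 8 were on chromosome V, 5 on IV, 3 on I, 3 on III, 1 on II and none on X, and 7 had a peak in at least 1 Notch library. Over all 372 regions the median of the mean folds was 7.74, and 302 had no peak in any Notch library. Folds are the authors' own values for each peak, and they rank peaks within a list rather than measure a difference between lists.

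Fisher's exact test of presence over 16621 merged regions gave 0 regions at an adjusted p under 0.05 by the Benjamini-Hochberg method, with 433 at an unadjusted p under 0.05, all 433 of them more often present with LAG-1. The smallest p that 4 libraries against 6 allow in this exact test is 0.00476. Leaving out LAG-1 library a, b or e, with 3 libraries still required, lowered the 372 regions to 195, 125 and 127, requiring a fold of at least 6 left 216, and taking the same 44 best peaks from every list left 21. Peak numbers per library did not separate LAG-1 from the 6 controls, with log10 means of 3.05 ± 0.257 (n = 4) and 2.58 ± 0.992 (n = 6, exact permutation p = 0.371, adjusted p = 0.743, two-sided). The difference of 0.479 ranged from 0.295 to 0.745 on leaving out 1 library, and it was 0.905 with a fold of at least 6.

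**Figure D2:**
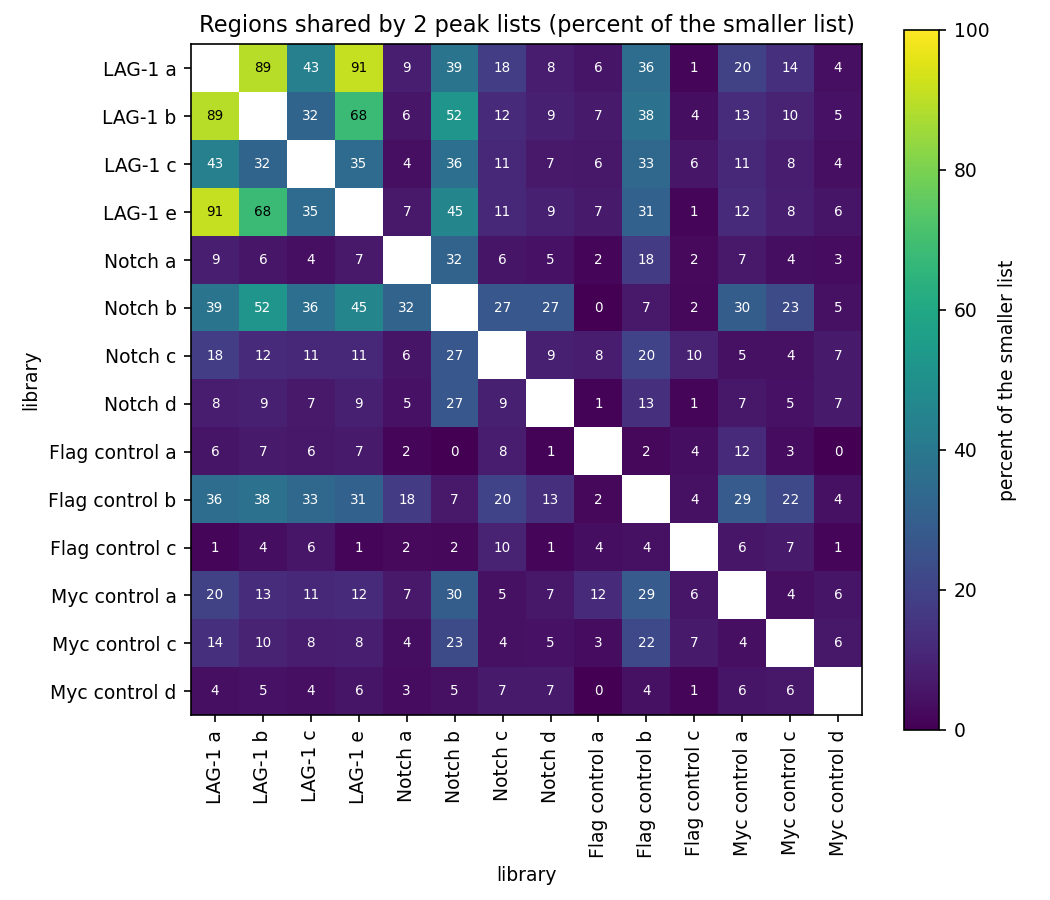
Percent of the regions of the smaller list that also hold a peak of the other list, for each of the 91 pairs of the 14 libraries, given in each cell and by colour. The LAG-1 libraries form a block of 32.4% to 91.1%, and the Notch pairs lie between 4.97% and 31.8%.

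The difference between overlap within groups and overlap between groups was positive for LAG-1 against the controls, at 10.3 percentage points, but did not pass the test (exact permutation p = 0.190, adjusted p = 0.254, two-sided). With a fold of at least 6 the difference was 17.4 points (adjusted p = 0.0762 in the exact permutation test). Without LAG-1 a, b or e the difference was 2.07, 3.40 and 2.95 points, and without Flag control b 17.9. Within LAG-1 the mean overlap was 59.9%, within the controls 7.41% and between them 12.1%. The difference takes the pairs within LAG-1 together with the more numerous pairs within the controls, Flag with Myc included. As the control pairs lay below the pairs between, the difference does not measure overlap within LAG-1 alone, which was not tested apart. Against the Flag controls alone the difference was 26.4 points and against the Myc controls alone 32.2 points, each at the smallest p that 35 splits allow (exact permutation p = 0.0571, adjusted p = 0.152). Without LAG-1 a, b or e these were 9.42, 15.3 and 14.05 points against Flag and 16.8, 21.2 and 20.5 against Myc controls, and without Flag control b the former was 47.1. LAG-1 libraries had 1.16 more log10 peaks than the Flag controls (exact permutation p = 0.0571, adjusted p = 0.457) and differed from the Myc controls by -0.204 (exact permutation p = 0.743, adjusted p = 0.8). The latter was 0.120, 0.0489 and -0.782 without Myc control a, c or d, -0.0873 without LAG-1 a, and 0.152 with a fold of at least 6. Fisher's exact test called 0 regions in both of these comparisons, with 190 and 124 at an unadjusted p under 0.05.

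The second comparison asked the same of the Notch protein. Only 5 regions had a peak in at least 3 of the 4 Notch libraries and in no control, and each of the 5 also had a peak in at least 3 LAG-1 libraries. They were IV from 16656269 to 16656635 with a fold of 7.94 ± 2.03 (SD, n = 4), III from 9565839 to 9566243 with 6.51 ± 2.86 (SD, n = 4), I from 10588211 to 10588509 with 37.2 ± 7.90 (SD, n = 3), I from 2639720 to 2640018 with 9.22 ± 8.08 (SD, n = 3) and II from 4047867 to 4048214 with 4.83 ± 0.873 (SD, n = 3). A further 15 regions, the first of those with peaks in 2 Notch libraries and no control, had mean folds of 4.87 to 9.28, and 1 of the 15 also had a LAG-1 peak, V from 3686247 to 3686682. The region with the best rank among the 15, IV from 1499042 to 1499456, had a fold of 9.28 ± 3.83 (SD, n = 2) and no LAG-1 peak.

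Notch lists shared 4.97% to 31.8% of the smaller list in the 6 pairs, with a mean of 17.6% against 2.27% after circular shifts. That mean was close to the 17.7% between Notch and LAG-1 lists, and Notch b, the shortest list with 44 peaks, shared 36.4% to 52.3% of its regions with the LAG-1 lists. The similarly short Flag control b, with 45 peaks, shared 31.1% to 37.8% with them, and the mean between LAG-1 and the Flag controls was 14.7%. Overlap within groups exceeded overlap between Notch and the controls by 2.46 points (exact permutation p = 0.286, adjusted p = 0.327, two-sided) and by 1.26, 0.411 and 1.05 without Notch a, b or d and 4.11 without Myc control d. Peak numbers differed by 0.164 on the log10 scale, with means of 2.74 ± 0.946 (n = 4) and 2.58 ± 0.992 (n = 6, exact permutation p = 0.8, adjusted p = 0.8). Fisher's exact test called 0 of 22648 regions after adjustment, with 6 at an unadjusted p under 0.05.

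Against the Flag controls alone 10 Notch regions met the rule in place of 5, and leaving out Notch library a, b, c or d, with 3 libraries still required, left 3, 3, 2 and 3. Against the Flag and the Myc controls separately, Notch overlap differed by 5.92 and 4.75 points (exact permutation p = 0.114 and 0.171, adjusted p = 0.229 and 0.254). The overlap difference from Flag was -3.35 without Notch b and 12.4 without Flag control b, and that from Myc was 0.481, 8.81 and 7.22 without Notch b, Myc control a or c. With a fold of at least 6 the difference from the pooled controls was 2.998 points (adjusted p = 0.457, exact permutation test). From the Flag and the Myc controls separately it was then 16.001 and 10.6 points (adjusted p = 0.0762 each, exact permutation test). Fisher's exact test called 0 regions in both, with 5 and 2 at an unadjusted p under 0.05. Peak numbers differed by 0.847 and -0.519 on the log10 scale (exact permutation p = 0.229 and 0.571, adjusted p = 0.610 and 0.762). The former was 0.455 without Notch c, and the latter was -0.154, -0.912, -0.195, -0.266 and -1.10 without Notch b, Notch c, Myc control a, c or d.

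The third comparison set LAG-1 beside Notch, since the Notch intracellular domain is thought to reach DNA through its DNA-binding partner. Merged over all 14 lists, 1222 regions had a peak in at least 2 LAG-1 libraries and 82 in at least 2 Notch libraries, and 31 regions met both rules. Circular shifts of the Notch regions gave 0.850 shared regions on average and 4 at most, a one-sided p of 0.000999, the smallest that 1000 shifts can give. Of the 31 regions, 12 had no peak in any control. First in the ranking was I from 12483530 to 12483989, with peaks in all 4 Notch libraries at a fold of 116 ± 34.7 and in all 4 LAG-1 libraries at 70.1 ± 30.02 (SD, n = 4 each). It also had a peak in all 3 Myc control libraries, at 8.24 ± 2.29 (SD, n = 3).

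V from 11770127 to 11770490 had a fold of 53.9 ± 13.1 in Notch and 25.7 ± 8.80 in LAG-1 libraries (SD, n = 4 each), with a peak of 5.34 in Myc control c. At I from 10588173 to 10588509 the fold was 37.2 ± 7.90 in 3 Notch libraries and 51.4 ± 23.4 in 4 LAG-1 libraries, with no control peak, although 4 control libraries had peaks in the adjoining stretch from 10589145 to 10589928. IV from 16656221 to 16656635 had peaks in all 4 libraries of both proteins and in no control. Other regions with peaks in most libraries were III from 10758760 to 10759321, II from 10563302 to 10563685 and III from 3867395 to 3867752, where LAG-1 folds were 13.9 ± 9.89, 15.9 ± 7.29 and 25.5 ± 10.9 (SD, n = 4). At these the Notch folds were 5.51 ± 1.30 (n = 4), 5.64 ± 2.14 (n = 3) and 8.04 ± 2.18 (n = 3), and 2, 3 and 2 control libraries had peaks.

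**Figure D3:**
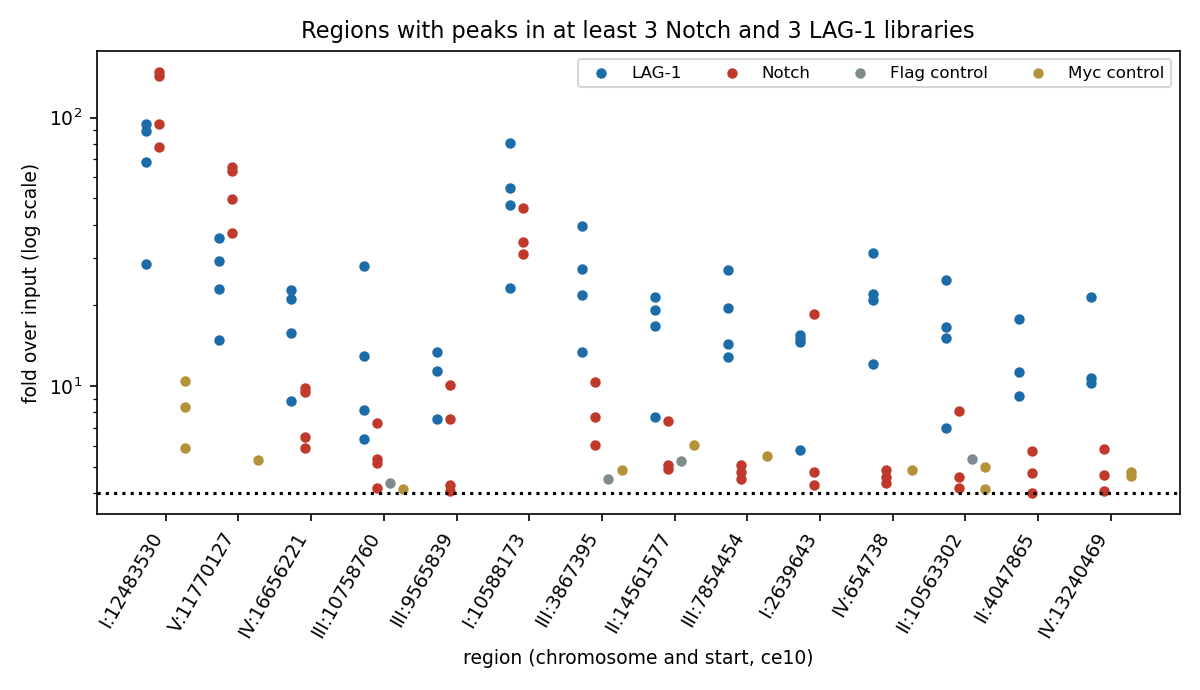
Fold over input, on a log scale, at the 14 regions with peaks in at least 3 Notch and 3 LAG-1 libraries; each point is the authors' fold of 1 library with a peak there, coloured by protein, and the dotted line marks the 4-fold limit of the peak caller. At I from 12483530 the Notch folds lie between 77.7 and 148 and the LAG-1 folds between 28.5 and 94.5.

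Sharing beyond chance was not limited to the pair of pathway proteins. LAG-1 and the Myc controls shared 36 of 244 Myc control regions, against a shift mean of 2.19 (permutation p = 0.000999), and Notch and the Myc controls shared 10, against 0.144 (permutation p = 0.000999). Only 4 regions had a peak in 2 Flag control libraries, of which 0 were shared with LAG-1 and 1 with Notch (permutation p = 1 and 0.004995). Leaving out Notch c lowered the 31 shared regions to 18 and the 12 without a control peak to 7. With a fold of at least 6 these numbered 6 and 5, with the same 44 top peaks from every list 9 and 5, and with at least 3 libraries of both proteins 14 and 5.

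Present more often with LAG-1 than with Notch were 146 of 12078 regions at an unadjusted p under 0.05 in Fisher's exact test, 0 after adjustment, and none were more often present with Notch. Overlap within the proteins exceeded that between them by 21.003 points, at the smallest p the 35 splits of 4 against 4 libraries allow (exact permutation p = 0.0571, adjusted p = 0.152, two-sided). It was 9.23, 13.2 and 12.5 points without LAG-1 a, b or e and 32.8 without Notch b. Peak numbers differed by 0.315 on the log10 scale (exact permutation p = 0.571, adjusted p = 0.762), a difference that became -0.0503 without Notch b. Without Notch c the difference of Notch from the controls became -0.229 and without Flag control b -0.0205.

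The Flag and Myc controls, which should show what each precipitation recovers without a Notch pathway protein, were compared last. Flag control lists shared 2.22% to 4.44% of the smaller list with each other and Myc control lists 4.07% to 6.30%, while the mean between the groups was 9.44%, a difference of -5.08 points within minus between (exact permutation p = 0.4, adjusted p = 0.4). Without Flag control b it was -0.0292, without Myc control a -2.23 and without Myc control d -9.63. Mean overlap after circular shifts was 0.0662% within Flag, 2.83% within Myc and 1.88% between them, and the difference does not allow for this. The log10 peak numbers of the 2 control groups differed by -1.37, Flag minus Myc (exact permutation p = 0.2, adjusted p = 0.610), and 3 libraries against 3 allow no p under 0.1. The same limit of 0.1 holds for Fisher's exact test of presence, which therefore could not call a region at an unadjusted p under 0.05.

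The X chromosome, which makes up 17.7% of the covered chromosome length, held 13.8% ± 2.42 of the LAG-1 peaks (SD, n = 4), 14.9% ± 4.48 of the Notch peaks (n = 4), 13.9% ± 1.60 of the Flag control peaks (n = 3) and 16.9% ± 0.360 of the Myc control peaks (n = 3). LAG-1 and Notch differed from the 6 controls by -1.64 and -0.508 points (exact permutation p = 0.248 and 0.8, adjusted p = 0.660 and 0.914, two-sided), and from each other by -1.13 points (exact permutation p = 0.657, adjusted p = 0.914). With the same 44 top peaks from every list the LAG-1 difference from the controls was -12.5 points (adjusted p = 0.0762 in the exact permutation test), and with whole lists it was -0.677 without LAG-1 c and -2.40 without LAG-1 e. The Notch difference was 1.43, -2.12 and -1.04 without Notch b, a or c. Without Notch d or any 1 control it lay between -1.07 and -0.123. It was -3.96 with a fold of at least 6 and 0.568 with the same top peaks. The difference between LAG-1 and Notch was 0.484, -3.06 and -0.595 without Notch a, b or c, -1.70, -0.169 and -1.89 without LAG-1 b, c or e, 1.53 with a fold of at least 6 and -13.1 with the same top peaks. Against the Myc controls alone the X differences were -3.17 for LAG-1, -2.04 for Notch and -3.07 for the Flag controls. With a fold of at least 6 these were -7.46, -8.98 and -10.04 points (adjusted p = 0.4, 0.610 and 0.4 in the exact permutation test). In single libraries the exact binomial 95% interval ran from 14.4% to 17.7% for the 1965 peaks of LAG-1 e and from 2.53% to 21.7% for the 44 peaks of Notch b, and it covers counting error only.

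Peak strength within the lists varied between libraries. The median fold over input was 6.43, 5.99, 4.77 and 7.13 in the LAG-1 lists, 4.54, 4.74, 5.37 and 4.54 in the Notch lists, 4.65, 4.72 and 4.37 in the Flag controls and 4.95, 5.18 and 4.44 in the Myc controls. Tags inside peaks made up 1.28% to 5.62% of each LAG-1 library and 0.188% to 13.5% of each Notch library, against 0.0751% to 0.209% of each Flag control and 6.46%, 6.40% and 0.137% of Myc controls a, c and d.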

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

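The tests of depth, input, duplicates and overlap named here were chosen after the peak numbers had been seen, and those of depth and input were divided by library after a first pooled version. Notch library c stood apart from the other 3 Notch libraries in its number of peaks, 8261 against 44 to 826, and in the percent of its tags inside peaks, 13.5% against 0.188% to 0.955%. The gap to the nearest library was 0.905 and 0.942 of the range of the group on these scales, but 0.440 and 0.620 on the log10 scale, where neither would stand out. Chance gives such a gap in about 1 of 20 groups, and 10 sets of values were looked at.

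Notch c was 1 of 3 libraries with over 5000 peaks, the others being Myc control a and c. Binding that recurs in a group is argued against for the controls: 3.81% of the peaks of Myc control c overlapped peaks of Myc control a, above the mean of 2.89% under circular shifts but far below the 31.9% of peaks in the least similar LAG-1 pair. Low depth is argued against for Myc control a, since 4 of the 11 other libraries were shallower than its 11.02 M tags, but it remains open for Myc control c and Notch c, the deeper of which had 4.58 M tags against at least 8.11 M in the others. A shallow input may play a part in Notch c, whose input was estimated at 8.20 M tags against at least 10.2 M for the 11 others, but not in the Myc controls, where the higher estimate was 27.7 M. Duplicate reads could not be decided. At least 1.08% of the candidate peaks were removed as clonal in the 3 libraries against at most 0.0873% elsewhere. These are shares of all candidates, many of which were removed against the input instead, so they partly follow the length of the list. Notch c lost 420 peaks as clonal and kept 8261, Flag control b lost 10 and kept 45, and LAG-1 b lost 2 and kept 1533. The median clonal fold was 1.31 or more in the 3 libraries and reached 1.43 in another library.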

How the results depend on the processing

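No comparison of peak numbers, overlap or X share passed its threshold under any alternative (lowest adjusted p 0.0762). This says little or nothing about stability: a lone result of 4 against 6 at its floor of 0.00952 adjusts to 0.0762. Splits of 4 against 3, and overlap of 4 against 4, allow no p under 0.0571. Fisher's exact test gave 0 regions after adjustment in its 19 alternatives and 0 (197 unadjusted) in the simulation with 200 planted regions. It could hardly have come out otherwise. Of 330 differences under alternatives that could move them, 25 changed sign and 106 kept their sign but moved over 1.5 times, not counting the Jaccard index and unlogged numbers. Of 84 counts, 27 moved over 1.5 times. The cause was not tested except where fewer libraries or peaks are the alternative itself. A common Poisson threshold, leaving out 3 libraries with over 5000 peaks and leaving out low-focus stretches were chosen after seeing the data. Low depth limits what Myc control c (3.13 M tags) and Notch c (4.58 M tags) can show. Alternatives on transcription start sites, motif and gene lists were not run.

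With a fold of at least 6, LAG-1 regions absent from controls numbered 216, shared regions 6 and 5 without a control peak. Sign changed for LAG-1 against Myc controls in log10 peaks (0.152) and for LAG-1 X differences from Notch (1.53 points) and Flag controls (2.58). With the same number of top peaks, the regions numbered 21 for LAG-1 and 3 for Notch, shared regions 9 and 5 without a control peak, the overlap difference of the controls became 1.15 points and the Notch X difference from the controls 0.568. For LAG-1 that setting gave X differences of -12.5 from the controls (adjusted p 0.0762), -13.1 from Notch, -11.4 from the Flag and -13.64 from the Myc controls. With at least 2 or all 4 libraries required, LAG-1 regions numbered 937 and 120 and Notch regions 50 and 2. Notch regions numbered 8 with at most 1 control and 10 with the Flag controls alone. At least 3 or 1 libraries of both proteins gave 14 and 385 shared regions, 5 and 283 of them without a control peak. With the Jaccard index the overlap differences became -0.0149 for Notch against controls and 0.663 for Flag against Myc controls. Unlogged, peak numbers differed by -1109 for LAG-1 against controls, -22.4 for Notch against controls and -1086 for LAG-1 against Notch. Without the 3 libraries with over 5000 peaks, the log10 differences from the Myc controls became 0.951 for LAG-1 and 0.243 for Notch, the overlap difference of the controls 1.54, and shared regions 18.

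Leaving out 1 library at a time gave 125 to 444 LAG-1 and 2 to 7 Notch regions absent from controls, 18 to 31 shared regions and 7 to 18 without a control peak. Differences in log10 peaks ranged from -0.229 to 0.529 for Notch against controls (below 0 without Notch c or Flag b), -0.0503 to 0.708 for LAG-1 against Notch (Notch b) and -0.782 to 0.120 for LAG-1 against Myc controls (above 0 without Myc a or c). Overlap differences ranged from 2.07 (without LAG-1 a) to 17.9 (Flag b) for LAG-1 against controls, 9.42 (LAG-1 a) to 47.1 (Flag b) against Flag controls, 16.8 (LAG-1 a) to 44.9 (Myc a) against Myc controls and 9.23 (LAG-1 a) to 32.8 (Notch b) against Notch. For Notch they ranged from 0.411 (Notch b) to 4.11 (Myc d) against controls, -3.35 (Notch b) to 12.4 (Flag b) against Flag and 0.481 (Notch b) to 8.81 (Myc a) against Myc controls. X differences ranged from -2.40 (LAG-1 e) to -0.677 (LAG-1 c) for LAG-1 against controls, -2.12 to 1.43 for Notch against controls (Notch b), -3.06 to 0.484 for LAG-1 against Notch (Notch a), -0.862 to 0.856 for LAG-1 against Flag controls (LAG-1 a, c or Flag c) and -0.589 to 2.96 for Notch against Flag controls (Notch a).

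With the replicate letter as a replicate block, the log10 peak difference was 0.474 for LAG-1 and 0.338 for Notch against controls and 0.149 between them, and against Myc controls -0.967 for LAG-1 and -0.154 for Notch (-0.204 and -0.519 without the block). The block leaves 4 to 36 splits and no p under 0.0556, so no test could pass. Over 2401 regions same-letter pairs correlated at 0.047 on average and others at -0.0116. Of 13 libraries 5 lay closest to their own letter, so a tie stays open.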

Other observations

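Of the tests in this part, those of the low-focus stretches and of deeper LAG-1 libraries were chosen after results had been seen, the latter in place of an earlier test of the same question, as was the adjustment of the counts of splits, and the counts by chromosome were not planned. Of the 372 LAG-1 regions absent from controls, 77 lay on I, where 55.9 would follow from its share of the covered length, and 68 on III, against 51.1. V held 53 against 77.6, and X held 41 against 65.8, which is 11.02% of the regions (exact 95% interval 8.03% to 14.7%, counting error only). X makes up 17.7% of the covered length. Length was the only yardstick for these counts, and control regions were not counted by chromosome. Control peaks also lay below that share of X, at means of 13.9% in the Flag and 16.9% in the Myc controls (n = 3 each). Whether the departures from length are particular to LAG-1 was not tested.

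The 10 libraries were split into 4 and 6 in 100 of the 210 ways, the real split included. Only the real split gave as many regions as the 372 found for LAG-1, and the highest other split gave 169. Its share of 0.01 is the smallest that 100 splits allow. Adjusted over the 10 counts of splits it was 0.05. With the other counts as they were, 100 splits could give no lower adjusted value. The adjusted share therefore could not exclude chance, whatever the real count. Peaks that pass only the looser threshold of the target lists are argued against: the common threshold removed 3 of 5088 LAG-1 peaks and 100% of the 372 regions were left. Peaks that the controls would have gained at the looser threshold were not examined and stay open. Deeper LAG-1 libraries stay open as a cause for the 372 regions, each of which has a peak in LAG-1 a or b. Both (18.6 and 19.8 M tags) were deeper than every control (at most 16.8 M). Depth is argued against only for another set of regions, and only beside the Flag controls. LAG-1 c and e, both shallower than each Flag control, shared 356 regions absent from all 3 Flag controls, while 2 regions recurred in the Flag controls and were absent from both. The stricter threshold of the Flag lists applies here as well. Myc control c and d (3.13 and 8.98 M tags) were shallower than LAG-1 c and e (11.23 and 9.37 M), so depth stays open against them. Binding of LAG-1 stays a hypothesis, found and examined on the same lists, and differences between antibodies were not tested.

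For Notch, chance cannot be excluded: 12 of 100 splits gave at least the 5 regions found, and the highest other split, Notch b and c with Myc control a and c, gave 25. That split joins the 3 longest lists, and whether their length alone gives such a count was not tested. For LAG-1 against the controls 1 of 100 splits reached the real 433 (highest other 172), and for LAG-1 against Notch 1 of 35 reached 146 (highest other 27). In each case this was the real split alone, and its share was the smallest the splits allow. With the other counts as they were, neither share could fall under 0.05 after the adjustment below. This test therefore could not exclude chance. For Notch against the controls 9 of 100 splits reached the real 6 (highest other 37), and against the Myc controls 12 of 35 reached 2 (highest other 23), so chance cannot be excluded. For LAG-1 against the Flag and the Myc controls 2 of 35 splits each reached 190 and 124 (highest others 216 and 168), so chance cannot be excluded. The highest other split set LAG-1 c and the 3 controls against LAG-1 a, b and e in both cases, and so kept these 3 LAG-1 libraries together. For Notch against the Flag controls 1 of 35 reached 5 (highest other 2), but 1 of the 5 regions was more often present in the Flag controls and 0 passed the adjusted test, so little rests on that count. Adjusted over the 10 counts of splits by the Benjamini-Hochberg method, no share lay under 0.05: it was 0.05 for both LAG-1 counts with 100 splits and 0.0714 for LAG-1 against Notch and for Notch against the Flag controls, each from the smallest share its splits allow (0.01 and 0.0286). For Flag against Myc controls the count decides nothing, since Fisher's exact test of 3 libraries against 3 allows no p under 0.1 and each of the 10 splits had to give 0, the highest other included.

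Stretches of low-focus peaks were defined only after the lists had been seen, and the criteria were replaced several times: 56 stretches had at least 2 peaks in at least 2 controls, 11 had at least 2 peaks in at least 4 libraries, 48 had low-focus peaks in at least 4 libraries, 14 of those had peaks in at least 2 controls, and 3 had in addition a median fold of at least 10. The 3 are therefore picked as the strongest, and the median ratio of input tags to the library's median was 1, 1.16, 1.14, 1.16 and 1.37 under these definitions.

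In the 3 stretches, I from 131595 to 133685, I from 10589145 to 10589928 and II from 8418787 to 8421522, peaks in 4, 8 and 8 libraries had median focus ratios of 0.558, 0.572 and 0.596. The second lies beside the LAG-1 and Notch region at I from 10588173, whose focus ratios were 0.827 to 0.912. Over the 33 peaks of the 3 stretches together, input tags were at the median 1.37 times the library's median, and the median fold over input was 20.9. The median fold was 19.5 in 17 peaks of 5 control libraries and 23.3 in 16 peaks of target libraries. Extra copies in the strains would raise the input about as much as the precipitate. Such a rise in both alike could not enter the lists, since called peaks already exceed input by 4-fold, so a comparison with the fold decides nothing. The upper quartile of the input ratio was 1.60 in the 3 stretches. It was 1.36, at a median fold of 7.33, in the 48 chosen without regard to controls or a fold of 10. The input itself was thus raised little in most of these peaks. Binding by the tagged target proteins is argued against as the cause of the control peaks, since the control worms carried tagged GFP. Of the 6 of these 48 with a median fold of at least 10, 5 had a control peak, at a median fold of 19.4 against 16.3 in target libraries. Whether such binding adds to the target peaks cannot be told apart from what gives the control peaks, because the folds of both overlap widely (quartiles 16.7 to 113 and 15.8 to 201). DNA that entered the precipitates but not the inputs also stays open: at most 57.1% of the libraries had a peak in any 1 stretch, and no sequence was examined. Construct DNA could be such a source, above all for the stretch on II, a chromosome with a common site of transgene insertion, and whether the stretch lies at that site was not examined.

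A hypothesis was that Notch peaks fall on the strongest LAG-1 regions. The 31 shared regions had a median LAG-1 rank percentile of 11.7, against 34.6 for random LAG-1 regions present in as many LAG-1 libraries (permutation p = 0.0001, the smallest that 10000 draws can give). The 36 LAG-1 regions with peaks in at least 2 Myc control libraries also ranked high, at 24.6 against 37.9 (permutation p = 0.0036), so that part of the shift may come from strong regions gaining peaks in any library. Whether the Notch value exceeds the Myc control value was not tested.

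A second hypothesis, that LAG-1 regions gather in the middle 33.3% of each chromosome, was not borne out: 33.1% of the 372 regions lay there (exact 95% interval 28.3% to 38.1%), against 33.3% of the length (binomial p = 0.956).

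One pile-up of tags appeared at I from 2850836 to 2851162. Notch c had 298657 tags per 10 M there, 2.99% of the library, with a fold of 7425 and a focus ratio of 0.993. Flag control a had 8601 and LAG-1 a 4607 tags per 10 M at the same place.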
